A study of Drosophila melanogaster with 60 samples.

How the data were processed

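Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out on 60 samples from Drosophila melanogaster embryos, of which 35 were immunoprecipitates and 25 were inputs. Per the labels' protocols, nuclei of 1 tissue were isolated by INTACT, in which nuclei tagged by a tissue-specific driver are captured from whole embryos, and the DNA was amplified with the ThruPLEX kit before library preparation. Groups were taken from the labels for tissue, stage, antibody and genotype, and replicates from the numbers or letters in the sample titles. Inside 2 lists the peaks carry the name of another replicate (early mesoderm Ubx R2 as S, and H3K27ac control 3 as R2). Their contents differed from those of every other list and the labels were followed, but a mix-up of replicates is not excluded. The values used here are the peak lists of the 35 immunoprecipitates, 1 list for each library. The inputs were not used here by themselves.

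Per the submitters' processing notes, the reads were handled with FastQC, Bowtie and MACS2 on the dm6 build. No versions or parameters were given in the sources used here, and nothing states whether an input was used as background for each list. Each list had the columns of a broad-peak file. The fold column, deposited by the authors, is the enrichment of a peak over its background, a ratio that was not scaled between libraries. The other columns deposited by the authors were 2 columns of −log10 values (p and q) and a score that in the single lists equalled the whole part of 10 times the −log10 q to within 1. No −log10 q was under 1. These are the authors' values for a single peak, and they were used only to describe, rank or filter peaks within a list. The authors also deposited 5 distinct combined Ubx lists; of these, 4 held the peaks of 2 single lists put together, and the one for early neuronal nuclei held merged overlaps. They were used only as an alternative.

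Coordinates were checked against the release 6 reference. Only 13 peaks in 7 lists ended past a chromosome end, by at most 71 bp. Genes were the 13968 protein-coding genes of the Ensembl annotation of this assembly. A gene region ran from 2 kb upstream of the gene's start to its end, and a TSS window covered 1 kb to either side of the start. No list was a copy of another, since at most 0.150% of the peaks of any of the 595 pairs of lists had identical coordinates.

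A gene was counted as bound by Ubx when a peak of every list of the group overlapped its gene region by at least 1 bp. The overlap of bound genes between groups was tested across genes by Fisher's exact test, and the share of genes with a peak per list by an exact permutation test, both two-sided. Fisher's exact test and its chance counts take every gene as equally likely to be bound and do not match gene length. Enrichment of a fixed gene list among bound genes was set against 10000 random lists matched on 10 classes of gene region length, one-sided, with Benjamini-Hochberg adjustment over lists and groups. For the histone marks and Pho, the measure was the percent of a window covered by peaks: the TSS window for H3K27ac and Pho and the gene region for H3K27me3. Libraries of a comparison were first trimmed to the covered length of the library that covered least, by dropping the peaks with the lowest scores. The arcsine of the square root of the covered share was tested with limma (version 3.58.1, R 4.3.3) with a mean-variance trend, over genes covered in at least 1 library, at an adjusted p of 0.05. Gene lists were tested with limma's camera with the correlation between genes estimated from the residuals, over 16 sets for each comparison: the 15 fixed lists and the genes bound by Ubx in late mesoderm. Sets with fewer than 2 tested genes had no test, which left 10 sets for H3K27ac between stages. Overlap of Ubx with Pho was set against 100 circular shifts of the Ubx peaks within their chromosome. Sequence motifs were counted in windows of 200 bp centred on peak midpoints and in windows 1 kb to either side. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

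The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names 20 genes in every comparison, which are the 8 Hox genes and twi, Mef2, tin, Mhc, elav, pros, wg, en, Dll, GATAe, repo and SoxN. It adds up to 5 genes per direction with the largest difference of mean covered share among genes past the threshold or, where fewer than 5 pass, among genes of the fixed lists whose libraries do not overlap between groups. For Ubx it adds up to 5 genes of the fixed lists per direction that were bound in every list of one group and in no list of the other, taking those with most peaks first. Of the 427 names in the fixed lists, 425 matched a gene of the annotation; nos and calypso did not.

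The tests were tried on simulated data. With 200 genes raised by 20 points of covered share, limma recovered 89% for H3K27me3 between stages and 0% in the other 4 comparisons, so that differences of that size under degradation were not recovered. With 200 genes raised by 50 points of covered share, limma recovered 0% for H3K27ac between stages, 98% for H3K27me3 between stages, 0% for H3K27ac under degradation, 90.5% for H3K27me3 under degradation and 77.5% for Pho. With 80 points the values were 81.5%, 99.5%, 86%, 100% and 100%, and no unchanged gene was called. The raised genes were drawn from all genes tested, and each kept the spread of genes with a like mean. For H3K27me3 between stages only 132 of 2421 genes had a mean covered share of at least 10%. The recovery there is thus mostly that of genes with little coverage. It does not give the power at well-covered genes, where gsb, at -82.6 points, had an adjusted p of 0.412 by limma.

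The degradation groups share replicate numbers. Whether the numbers pair the samples was checked from the correlation of the deviations of same-numbered libraries from their group means. It was 0.438 to 0.598 for H3K27ac and 0.298 to 0.359 for H3K27me3, so that the numbers were taken as pairs there, as a property of the data that no label states. For Pho it was -0.0173 to 0.00430, and the numbers were not taken as pairs. No paired analysis was possible between stages because they share 1 number only. The labels give a sequencing lane for the Pho libraries: lane 5 held 2 control libraries and 1 degradation library, and lane 6 held 1 and 2.

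Read depth was not analysed here, since the lists hold no read totals. The number of peaks and the covered length stand in for it, and they limit what a comparison of lists can show: a gene without a peak in a short list is not shown to be unbound. Nothing in the labels says whether replicates came from separate collections of embryos. The p-values of limma, camera and the permutation tests over lists or libraries thus measure only the spread between these samples, which may be technical. Those of Fisher's exact test are across genes, those of list enrichment over random gene lists, and those of the Pho overlap over shifted peaks. These latter p-values do not measure the spread between libraries. Alternatives were the lists as deposited, the better-scored 50% of each list, other windows, another scale, a replicate block, the lane, and each replicate left out in turn. Leaving out peaks that were at least 50% soft-masked repeat, or the third libraries of both degradation groups, was chosen after seeing the data.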

Results

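The ChIP-seq lists covered the Hox transcription factor Ultrabithorax (Ubx), the histone mark H3K27ac, which is found at active promoters and enhancers, the Polycomb-associated mark H3K27me3, and Pleiohomeotic (Pho), a DNA-binding protein that recruits Polycomb complexes. Ubx was mapped in mesodermal nuclei (3 lists early, 2 late) and neuronal nuclei (2 early, 2 late). Early refers to embryonic stages 10 to 13 and late to stages 14 to 17. Both histone marks were mapped in wild-type mesoderm (2 lists early, 2 late). They were also mapped in late mesoderm of embryos carrying GFP-tagged Ubx and a GFP-targeted degrader, either without a driver (control, 3 lists) or with the degrader driven in muscle by Mef2 (degradation, 3 lists). Pho was mapped in the same 2 genotypes with 3 lists each. The Ubx lists held 936 to 66459 peaks over 0.172 to 16.6 Mb, the H3K27ac lists 4721 to 85449 peaks over 1.01 to 26.9 Mb, the H3K27me3 lists 3957 to 56131 peaks over 1.0 to 21.4 Mb, and the Pho lists 45669 to 61534 peaks over 11.9 to 18.5 Mb.

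The Ubx gene, on 3R from 16656623 to 16734426 of dm6, and the Hox gene Antp each carried Ubx peaks in all 9 Ubx lists. The Ubx gene had 10 and 13 peaks in the late mesoderm lists, 30 and 58 in the early neuronal lists, and 3 and 4 in the late neuronal lists. All 8 Hox genes, which set segment identity, were bound in both late mesoderm lists and in both early neuronal lists. Random genes matched to them in length were bound at 69.6% in late mesoderm and 98.5% in early neuronal nuclei. The early neuronal count is thus near what genes of this length give. In early mesoderm 4 were bound in every list (pb, Antp, Ubx and Abd-B), and in late neuronal nuclei Antp and Ubx. The mesodermal regulator twi was bound in every list of all 4 groups, and Mef2, which drives muscle differentiation, in every list of late mesoderm and of both neuronal groups. The gene regions of Antp, Ubx and twi are long (104976, 79804 and 64952 bp), and long regions are hit more often. The neuronal gene elav was bound in every list of none of the 4 groups.

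Genes bound in every list numbered 1145 in early mesoderm (8.20% of genes), 2632 in late mesoderm (18.8%), 9905 in early neuronal nuclei (70.9%) and 112 in late neuronal nuclei (0.802%). Lists that were independent of each other would share 610, 1861, 9579 and 26.4 genes if every gene were equally likely to be hit. Single lists differed widely: a Ubx peak lay in 45.1% ± 34.9 of genes in early mesoderm (SD, n = 3), 36.8% ± 6.54 in late mesoderm (n = 2), 83.3% ± 12.8 in early neuronal nuclei (n = 2) and 4.42% ± 1.09 in late neuronal nuclei (n = 2). Replicates shared from 1.92% to 39.6% of their peaks. These shares follow the length of the lists: with each list trimmed to the number of peaks of the shortest, 64, 122, 259 and 86 genes were bound in every list.

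**Figure D1:**
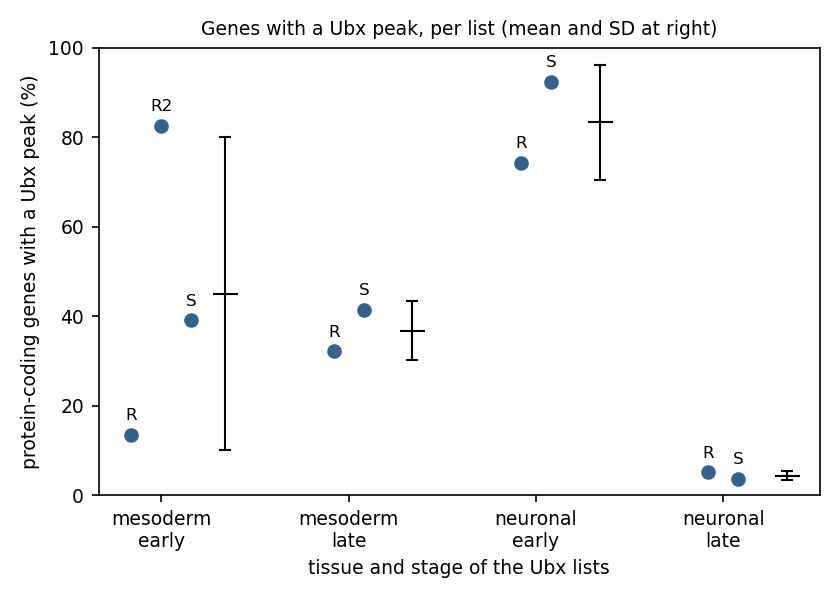
Share of protein-coding genes with a Ubx peak (vertical axis, percent) in each of the 9 Ubx lists, by tissue and stage (horizontal axis). Points are single lists with their replicate letter, and the bar beside them is the mean and SD; the 3 early mesoderm lists run from 13.5% to 82.6%, and both late neuronal lists lie near 4.42%.

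Mesodermal and neuronal nuclei were compared to ask which Ubx targets belong to 1 tissue. At the early stages 808 of the 13968 genes were bound in both neuronal lists and in none of the mesoderm lists, and 3 the other way round. Of the fixed lists, 9 of 119 odorant and gustatory receptor genes, among them Gr77a, Gr28a, Gr5a and Or67d, and 6 of 82 cytoplasmic ribosomal protein genes, among them RpL24, were bound only in the early neuronal lists. These shares were not tested against that of all genes. No Hox gene, mesoderm identity factor or neuronal identity factor was bound in 1 of the 2 tissues alone. The long lists largely fixed this in advance. Mesoderm list R2 hit 82.6% of genes and each of the 8 Hox genes, which leaves few genes to be neuronal only. The neuronal lists hit 74.3% and 92.3% of genes. The counts thus do not show which targets belong to 1 tissue. Both tissues bound 1069 genes, where 812 would be shared by chance if every gene were equally likely to be bound (odds ratio 6.35, Fisher's exact test across genes, p = 5.37e-86). The ratio was 2.21 in the TSS window, 3.31 without mesoderm list R, 3.28 without mesoderm list S and 10.2 without neuronal list R. It was 6.16 without repeat peaks, 9.97 with the better-scored 50% of each list and 213 with trimmed lists. Among an equal number of best-scored peaks, 37.8% to 62.2% per Ubx list were repeat peaks. How far repeats raise the ratios of trimmed lists was not tested. The chance counts of the overlaps below also take every gene as equally likely to be bound. Longer genes are hit more often. In early mesoderm 39.8% of random genes matched in length to the Hox genes were bound, against 8.20% of all genes. How much of each overlap comes from gene length was not tested. The share of genes with a peak per list was not shown to differ (exact permutation test, p = 0.3, smallest possible 0.1).

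At the late stages the difference ran the other way, with 2072 genes bound only in mesoderm and 8 only in neuronal nuclei. The genes bound only in mesoderm included 6 of 8 Hox genes, with Scr carrying 7 and 8 peaks, 10 of 27 mesoderm and muscle identity factors, 8 of 30 muscle differentiation genes and 8 of 22 neuronal identity factors. Those with most peaks were ush, a blood-cell regulator (10 and 11), pros, which acts in neural progenitors (6 and 12), the muscle gene Msp300 (6 and 10), Scr, and the gut factor dve (5 and 8). Both tissues bound 99 genes, where 21.1 would be shared by chance (odds ratio 34.0, Fisher's exact test across genes, p = 9.67e-58). The size of this ratio rests on single lists: it was 5.22 and 5.75 without neuronal list R or S and 11.98 without mesoderm list R. It fell to 24.8 without repeat peaks. With repeat peaks kept, it rose to 98.8 with the better-scored 50% of each list, 173 in the TSS window and 175 with trimmed lists. The permutation test over lists gave p = 0.333, the smallest that 2 lists against 2 can give. With lists trimmed to equal numbers of peaks, 50 genes were bound only in late mesoderm and 27 only in late neuronal nuclei, and the order of these groups turned: 0 of 8 Hox genes and 0 of 27 mesoderm and muscle identity factors were bound in both late mesoderm lists, against 2 and 2 in both late neuronal lists. The difference between tissues was not tested for single groups of genes. The tissue difference in the share of genes was -38.2 points early and 32.4 points late, and an exact permutation test of the change between stages gave p = 0.05 over 60 arrangements, which is not under the threshold. With trimmed lists both signs turned, to 0.705 points early and -0.451 points late.

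Between stages in mesoderm, 160 genes were bound only early and 108 only late, a direction that turned with trimmed lists (4 and 22), with the better-scored 50% of each list (80 and 113), in the TSS window (55 and 132), without early list R2 (176 and 744) and without late list R (245 and 418). The glial regulator repo and the ribosomal protein gene RpL19 were bound only early. The cardiac and muscle factor Hand and 4 receptor genes (Or82a, Gr39a, Gr92a and Or24a) were among 6 genes of the fixed lists bound only late. Both stages shared 703 genes where 216 would be shared by chance (odds ratio 8.98, Fisher's exact test across genes, p = 4.78e-248), and the share of genes with a peak gave p = 0.9 by the exact permutation test. The ratio was 4.25 and 5.57 without early list R or S, 5.97 and 5.43 without late list R or S and 5.11 in the TSS window. It was 8.53 without repeat peaks, 15.7 with the better-scored 50% of each list and 561 with trimmed lists. In neuronal nuclei 8915 genes were bound only early and 1 only late. The early genes with most peaks were Msp300 (32 and 58), pros (27 and 54), ush (26 and 42), svp, a nuclear receptor gene (20 and 32), and dve (16 and 32). Both stages shared 106 genes where 79.4 would be shared by chance (odds ratio 7.31, Fisher's exact test across genes, p = 3.66e-10), and the permutation test over lists gave p = 0.333. The ratio was 3.36 and 3.42 without late list R or S, 7.16 without repeat peaks, 15.6 with the better-scored 50% of each list and 63.3 with trimmed lists. In the TSS window the overlap was not past the threshold, with 5 genes shared where 2.59 would be by chance (Fisher's exact test, p = 0.109). The late neuronal lists hold 1336 and 936 peaks against 38447 and 66459, so absence from them is not evidence of absence of Ubx.

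Among the fixed lists, mesoderm and muscle identity factors were bound in late mesoderm at 15 of 27 (55.6%) against 37.3% of length-matched genes (one-sided permutation p = 0.0171 over 10000 random lists), Hox genes at 8 of 8 against 69.6% (p = 0.0449) and hemocyte genes at 8 of 13 against 39.7% (p = 0.0473). In the TSS window 0 of 27, 0 of 8 and 1 of 13 of them were bound, against 3.25%, 3.07% and 3.33%, and the list with the lowest p was that of ectoderm and segmentation genes, at 4 of 26 against 3.43% (permutation p = 0.0103, adjusted p = 0.618). None of the 60 tests of a list in a group passed after adjustment, and the lowest adjusted p was 0.663. Muscle differentiation genes were bound at 14 of 30 against 44.7%, glial genes at 4 of 10 against 33.0%, ectoderm and segmentation genes at 14 of 26 against 42.2%, and fat body genes at 2 of 9 against 25.1%. Polycomb and Trithorax group genes were bound at 2 of 17 against 32.3% of length-matched genes, and germline genes at 1 of 8 against 16.3%. In early mesoderm both lay the other way, at 5 of 17 against 14.6% (permutation p = 0.0766) and 2 of 8 against 5.93% (permutation p = 0.0773), with an adjusted p of 0.663 each.

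H3K27me3 was compared between stages in wild-type mesoderm to ask how Polycomb-marked regions differ as the tissue matures, trimmed to a covered length of 1.0 Mb per list. The segmentation genes gsb and prd, the cardiac and muscle factor lbe, the cardiac T-box gene Doc2 and the glial determinant gcm were covered almost throughout early and much less late. The lists differed in kind, since 771 and 284 peaks filled this length early and 3493 and 3957 late. Among an equal number of best-scored peaks per list, 28.0% and 9.56% were repeat peaks early and 48.3% and 35.9% late. Such a difference between lists and a loss of the mark cannot be told apart here. Coverage of gsb, on 2R from 25061964 to 25064643, was 97.1% ± 4.05 early and 14.5% ± 20.5 late (SD, n = 2 each), and that of lbe, on 3R from 21441577 to 21446537, was 97.3% ± 3.76 and 24.8% ± 11.4. The values were 100% ± 0 and 29.97% ± 40.9 for prd, 91.4% ± 12.2 and 21.4% ± 6.48 for Doc2, and 95.6% ± 6.26 and 27.1% ± 24.8 for gcm. Higher late were wg (0.279% ± 0.395 and 9.89% ± 0.477), gsb-n (2.53% ± 3.57 and 11.2% ± 7.37), peb (0% ± 0 and 7.45% ± 6.04), ey (0% ± 0 and 6.35% ± 1.72) and lz (2.15% ± 3.04 and 6.71% ± 1.72).

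By group, H3K27me3 covered 26.9% ± 7.21 of the Hox genes early and 9.71% ± 2.09 late (n = 2 each), with 5 of the 8 genes lower late. The other Hox genes, pb, Antp and Ubx, were little covered by the 1.0 Mb kept per list and had higher means late (1.09% ± 1.54 and 3.70% ± 0.560, 1.47% ± 2.08 and 2.43% ± 1.71, and 2.19% ± 0.455 and 3.18% ± 0.131). Low coverage in these trimmed lists does not show absence of the mark. The late mesoderm controls of the degradation series, trimmed to 8.58 Mb, covered 69.5% of the Hox genes. It covered 23.8% ± 5.09 and 10.8% ± 5.52 of mesoderm and muscle identity factors, 27.8% ± 3.14 and 13.3% ± 5.90 of ectoderm and segmentation genes, and 20.6% ± 3.34 and 11.2% ± 3.70 of neuronal identity factors. Abd-B was at 54.2% ± 2.72 early and 14.6% ± 8.29 late, en at 83.1% ± 17.1 and 44.96% ± 3.66, and SoxN at 60.2% ± 6.98 and 18.2% ± 2.75. Of 159 tested genes of the fixed lists, 24 were higher and 42 lower late in both libraries against both (41.5%, where chance gives at most 33.3%), against 16.0% of all 2421 genes tested. Genes with ties between groups, as at 0%, cannot separate, so the chance share is under 33.3% by an amount that was not computed. No gene passed limma at an adjusted p of 0.05 (lowest 0.412), and 37 genes higher and 43 lower had an unadjusted p under 0.05. Adjusted over the list alone, 1 mesoderm identity factor and 2 glial genes passed, all lower late. No list passed camera, with the Hox genes and the ectoderm and segmentation genes lowest (adjusted p = 0.283 with an estimated correlation). For gut and endoderm factors and for Polycomb and Trithorax group genes the mean was lower late although 6 of 10 and 4 of 5 tested members were higher, and for muscle differentiation and fat body genes the mean was higher while camera pointed lower. Most alternatives did call genes lower late, from 2 to 59 of them, and under the lists as deposited gsb, prd, lbe and Doc2 passed (adjusted p = 0.00747, 0.00697, 0.0332 and 0.0151). Under the same lists all 5 genes named as higher late turned lower, wg to -50.8, gsb-n to -54.1, peb to -53.5, ey to -33.6 and lz to -19.9 points. With the better-scored 50% of each list the difference was -7.52 points for Doc2 and -29.1 points for gsb. Late replicate 3 sets the trimmed length. With it left out and the other lists trimmed to 6.203 Mb, 2942 genes were called higher, but the genes named as higher late again turned lower, from -17.4 points (lz) to -55.9 points (peb), and the 5 named as lower moved to between -26.2 points (gcm) and -45.5 points (gsb). For prd, at 1.03% and 58.9% in late replicates 2 and 3, the difference of -70.03 points became -41.1 without late replicate 2 and -41.6 without late replicate 3. Without late replicate 2, 824 genes were called higher.

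**Figure D2:**
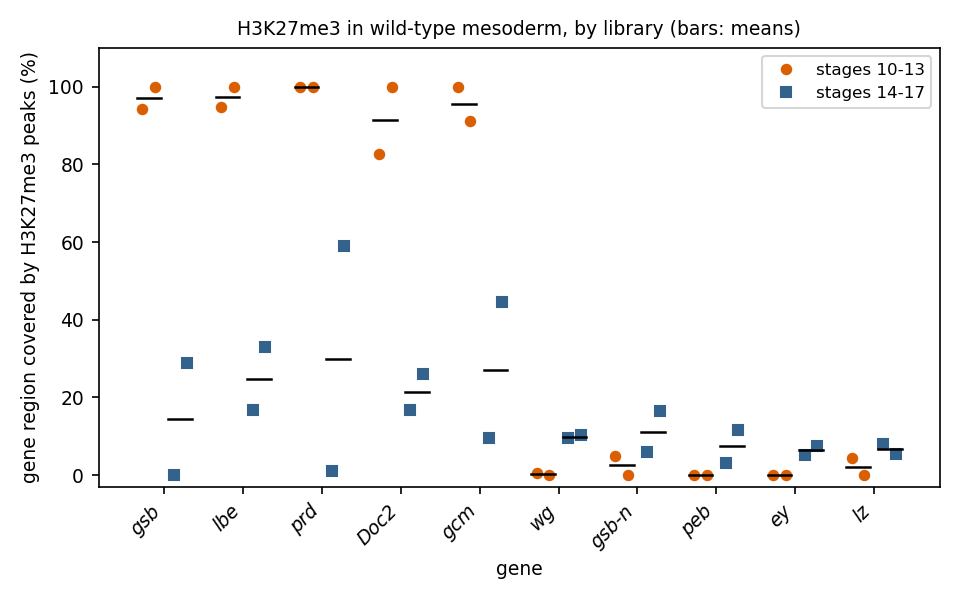
Percent of the gene region covered by H3K27me3 peaks (vertical axis) for the 10 genes named by rule (horizontal axis) in wild-type mesoderm, with 1 point per library and bars at the means. Early libraries (circles) cover gsb, lbe, prd, Doc2 and gcm by means of 91.4% or more, and late libraries (squares) by means of 14.5% to 29.97%.

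H3K27ac was compared between the same stages at 1.01 Mb per list, so that the best-scored peaks of the longer lists entered. Ribosomal protein genes, 78 of the 4149 genes tested, were the fixed list with most coverage: that of the TSS window over the 82 genes was 55.4% ± 11.5 early and 37.9% ± 25.1 late (SD, n = 2 each), with 12 genes lower late in both libraries against both and none higher. Named by rule were RpS19a (67.8% ± 33.6 and 0% ± 0), RpL40 (51.5% ± 8.87 and 1.52% ± 2.16), RpS6 (47.2% ± 2.79 and 1.97% ± 2.79), RpS15Aa (38.0% ± 12.4 and 0% ± 0) and RpS2 (45.8% ± 4.95 and 8.80% ± 12.4). Muscle differentiation genes were at 1.05% ± 1.49 and 2.29% ± 3.25, and of the Hox genes Dfd was at 12.2% ± 17.3 and 27.5% ± 7.42. The late libraries differed between themselves, at 55.7% (replicate 2) and 20.1% (replicate 3) over the ribosomal protein genes. No gene of 4149 passed limma (lowest adjusted p 0.541), with 13 higher and 176 lower at an unadjusted p under 0.05, and no list passed camera (lowest adjusted p = 0.964 with an estimated correlation). For ectoderm and segmentation genes the mean was lower late with 3 of 4 tested members higher, for neuronal differentiation genes it was higher with 3 of 5 lower, and for proneural and fat body genes it was lower while camera pointed higher. Of all genes tested, 121 were higher and 455 lower late without overlap, 13.9%. Chance gives at most 33.3%, and less with ties between groups, so 13.9% is not shown to be under chance. Without early replicate 1, 688 genes were called lower late, and without late replicate 2, 1507 were called higher.

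Degradation of Ubx in muscle was compared with its control to ask whether the marks at Ubx targets and lineage genes depend on the protein. The lists do not measure Ubx protein. At the Ubx gene itself, H3K27me3 covered 68.2% ± 32.0 in control and 90.9% ± 7.41 in degradation, H3K27ac covered 14.1% ± 19.6 and 18.8% ± 17.1 of its TSS window, and Pho 1.52% ± 2.41 and 15.3% ± 11.3 (SD, n = 3 each). None of these differences passed limma (adjusted p = 0.464, 1 and 0.963). The direction for H3K27ac rests on single libraries. Its difference of 4.73 points was -1.62 without control replicate 1, -0.175 without control replicate 3, -5.11 without degradation replicate 2 and 16.0 without control replicate 2.

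H3K27me3 over the 8 Hox genes was 69.5% ± 25.8 in control and 85.4% ± 10.5 in degradation (SD, n = 3 each), with all 8 means higher in degradation. Antp was at 66.4% ± 28.6 and 87.8% ± 6.36, Dfd at 75.5% ± 28.1 and 92.2% ± 7.47, and Abd-B at 73.7% ± 19.5 and 83.3% ± 13.5. Mesoderm and muscle identity factors were at 61.6% ± 18.2 and 74.7% ± 7.80 (25 of 27 means higher), neuronal identity factors at 57.9% ± 19.6 and 70.9% ± 7.67, ectoderm and segmentation genes at 59.5% ± 17.6 and 69.6% ± 6.11, and gut and endoderm factors at 70.5% ± 26.1 and 83.1% ± 3.86. For the Hox genes 1 library decides the difference. Control replicate 3 covered 39.8% of the Hox genes where the other controls covered 86.2% and 82.5% and the degradation libraries 97.4%, 77.9% and 80.9%, and 40.6% of mesoderm and muscle identity factors against 71.8% and 72.3% in the other controls. With that control left out, the difference over Antp was 4.90 points in place of 21.4, over the Ubx gene 4.27 in place of 22.7, and over Abd-B, abd-A and lab it was -1.33, -2.04 and -0.369. For the neuronal identity, ectoderm and gut lists the SD was also wider in control (19.6, 17.6 and 26.1) than in degradation (7.67, 6.11 and 3.86). The means of these lists were not compared without control replicate 3, so the same library may decide their differences.

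**Figure D3:**
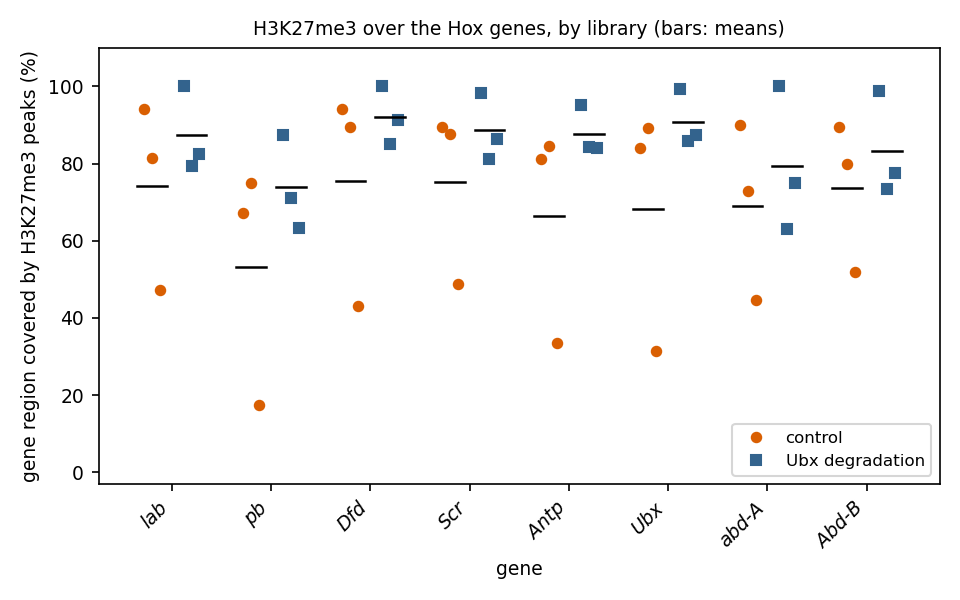
Percent of the gene region covered by H3K27me3 peaks (vertical axis) for the 8 Hox genes (horizontal axis) in control (circles) and Ubx degradation (squares), with 1 point per library and bars at the means. Control replicate 3 is the lowest point of each gene, and the other controls lie among the degradation libraries for most genes.

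Muscle differentiation genes carried little H3K27me3, at 2.61% ± 0.230 in control and 3.09% ± 0.246 in degradation, although 18 of 23 tested members had a lower mean in degradation. Neuronal differentiation genes were at 2.64% ± 0.217 and 2.87% ± 0.930 with 22 of 23 members lower, and Polycomb and Trithorax group genes at 9.69% ± 2.41 and 13.0% ± 0.20 with 9 of 13 lower, and fat body genes at 11.6% ± 5.36 and 12.2% ± 2.65 with 6 of 8 lower. Named by rule were the Polycomb gene ph-d (3.26% ± 3.73 and 14.9% ± 8.15), the gustatory receptor Gr59c (15.5% ± 19.3 and 0% ± 0), the axon guidance receptor robo2 (6.90% ± 3.40 and 1.13% ± 1.95) and the muscle gene sls (3.07% ± 4.5 and 0% ± 0). No gene of 8109 passed limma (lowest adjusted p 0.464), with 29 higher and 175 lower at an unadjusted p under 0.05. The count of lower genes rests on single libraries. It was 15 without control replicate 3, where 3475 genes were tested, 22 without degradation replicate 3 and 1032 without control replicate 2. Control replicate 3 kept 28940 peaks after trimming, against 649 to 12974 in the other libraries. Whether it also decides the counts of lower members above was not tested. Without overlap, 15 genes were higher and 25 lower, 0.493% where chance gives at most 10% for 6 exchangeable libraries, which paired libraries are not. Ties between groups, as at 0%, lower that chance share further. No list passed camera, and the lowest adjusted p was 0.144 with an estimated correlation (mesoderm identity, proneural, neuronal identity, glial, ectoderm and gut lists). These fits do not pair the libraries. With replicate numbers as a block nothing passed either (lowest adjusted p 0.217 by limma and 0.344 by camera).

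H3K27ac under degradation was compared at 7.71 Mb per list. The myoblast fusion regulator lmd, on 3R from 23021222 to 23026713, was the only gene of the fixed lists whose libraries did not overlap, at 4.16% ± 7.21 of the TSS window in control and 34.3% ± 6.60 in degradation (SD, n = 3 each, adjusted p = 1). The controls were at 12.5%, 0% and 0%. Control replicate 3, whose peaks carry the name R2, also sets the trimmed length, and with it left out and the other lists trimmed to 9.47 Mb the difference was 3.14 points in place of 30.1. With the lists as deposited it was 14.7 points. Muscle differentiation genes were at 21.2% ± 12.7 in control and 25.7% ± 9.47 in degradation (21 of 28 means higher), with Mhc at 5.93% ± 10.3 and 21.7% ± 37.5. Mesoderm and muscle identity factors were at 6.69% ± 3.35 and 10.5% ± 3.19 and glial genes at 3.57% ± 4.48 and 10.8% ± 5.85, while proneural factors were at 6.90% ± 1.34 and 4.0% ± 2.65 and neuronal identity factors at 3.33% ± 2.91 and 2.45% ± 2.40. Ribosomal protein genes were at 42.6% ± 21.7 and 45.6% ± 13.0. Means were higher in degradation with most tested members lower for neuronal differentiation genes (11 of 20), gut and endoderm factors (6 of 9) and fat body genes (4 of 7). In control replicate 3, muscle differentiation genes were at 6.82% and ribosomal protein genes at 18.9%, against 25.9% and 47.6% in control replicate 1. No gene of 12210 passed limma (lowest adjusted p 1), with 43 higher and 14 lower at an unadjusted p under 0.05. Without overlap, 92 genes were higher and 27 lower, 0.975% where chance gives at most 10% for exchangeable libraries, with the same limits of pairing and ties. No list passed camera (lowest adjusted p = 0.798 with an estimated correlation). With replicate numbers as a block nothing passed either (lowest adjusted p 0.843 by limma and 0.729 by camera).

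Pho was compared at 11.9 Mb per list. Named by rule as higher in degradation were lbl, the neighbour and relative of lbe (4.28% ± 7.42 in control and 35.8% ± 10.5 in degradation), the chromatin remodeller brm (6.45% ± 5.77 and 35.3% ± 18.4), the gustatory receptor Gr64f (5.31% ± 5.22 and 28.4% ± 5.82) and the muscle gene Zasp52 (0% ± 0 and 22.7% ± 11.1; SD, n = 3 each). Lower were Or45b (38.5% ± 4.03 and 12.8% ± 5.70), Or59c (26.5% ± 16.0 and 3.66% ± 3.47), RpL14 (32.9% ± 7.79 and 10.7% ± 8.74), Gr59d (28.0% ± 22.2 and 7.78% ± 0.986) and Gr98a (19.6% ± 12.2 and 0% ± 0). Pho covered 12.6% ± 2.13 of the Hox TSS windows in control and 16.2% ± 5.62 in degradation, although Abd-B, the Hox gene with an unadjusted p under 0.05, was at 22.1% ± 20.2 and 0% ± 0, 11.7% ± 2.37 and 15.05% ± 0.891 of those of mesoderm and muscle identity factors, and 10.0% ± 2.64 and 8.49% ± 0.832 of those of neuronal differentiation genes. Odorant and gustatory receptor genes were at 11.8% ± 2.82 and 9.88% ± 0.576. Hemocyte and Polycomb and Trithorax group genes had higher means in degradation with 6 of 11 and 9 of 16 members lower, and for proneural factors camera pointed lower although 13 of 20 members were higher. No gene of 13108 passed limma (lowest adjusted p 0.923), with 266 higher and 154 lower at an unadjusted p under 0.05. Without overlap, 652 genes were higher and 398 lower, 8.01% where chance gives at most 10%, and less with ties between groups. No list passed camera (lowest adjusted p = 0.694 with an estimated correlation). With the lane as a covariate no gene passed either (lowest adjusted p 0.0752).

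The 2632 genes bound by Ubx in late mesoderm were set against unbound genes of like length to ask whether marks at Ubx targets moved apart from those elsewhere. H3K27me3 was 1.07 ± 0.352 points higher over bound than unbound genes in control and 0.772 ± 0.207 points higher in degradation (exact permutation test, p = 0.3, n = 3 each). Pho was 2.34 ± 0.657 and 2.68 ± 0.410 points higher (exact permutation test, p = 0.5, n = 3 each), and H3K27ac 0.308 ± 1.73 and 0.0302 ± 0.945 points higher (exact permutation test, p = 0.7, n = 3 each). The smallest p that 3 against 3 can give is 0.1. This test does not pair the libraries. With replicate numbers as pairs, an exact sign permutation test gave p = 0.5 for H3K27me3 and p = 0.5 for H3K27ac, where the smallest possible is 0.25. The set of bound genes did not pass camera in any of the 5 comparisons (adjusted p = 0.964 and 0.934 between stages for H3K27ac and H3K27me3, and 0.920, 0.919 and 0.981 under degradation for H3K27ac, H3K27me3 and Pho, with an estimated correlation). The sign of the difference between genotypes turned with the lists as deposited for H3K27me3 (0.389 points) and Pho (-0.0715 points). With single replicates left out the sign also turned for H3K27ac, and for Pho without control replicate 3.

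Ubx and Pho peaks overlapped more than shifted peaks did. Of the late mesoderm Ubx peaks, 5.15% in list R and 4.81% in list S overlapped a region present in all 3 Pho control lists, against 2.05% ± 0.172 and 2.02% ± 0.164 of peaks shifted along their chromosome (SD over 100 shifts), a ratio of 2.51 and 2.38 (permutation p = 0.01 each, the smallest that 100 shifts can give). Against regions of any Pho control list the shares were 62.3% and 61.2%, against 41.3% and 41.2% of shifted peaks, a ratio of 1.51 and 1.49 (permutation p = 0.01 each). Shifted peaks do not keep the tendency of peaks to lie in open chromatin.

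The highest-ranked peak of both late mesoderm Ubx lists lay over exd, which encodes the Hox partner Extradenticle. It ran on X from 15992656 to 15994695 of dm6, 2040 bp, with the same ends in both lists, and was singled out after its values were seen. Its deposited fold was 27.7 in list R and 48.9 in list S, where the next highest were 10.4 and 18.7. It lay wholly within the gene (15992468 to 15996509, plus strand), and 63.7% of its bases were exon, 41.9% coding and 36.3% intron only, over 4 annotated transcripts. Peaks with both ends within 100 bp of these were also present in 6 of the 26 lists of other targets, 2 of H3K27ac and 4 of H3K27me3, and in no Pho or wild-type histone list.

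**Figure D4:**
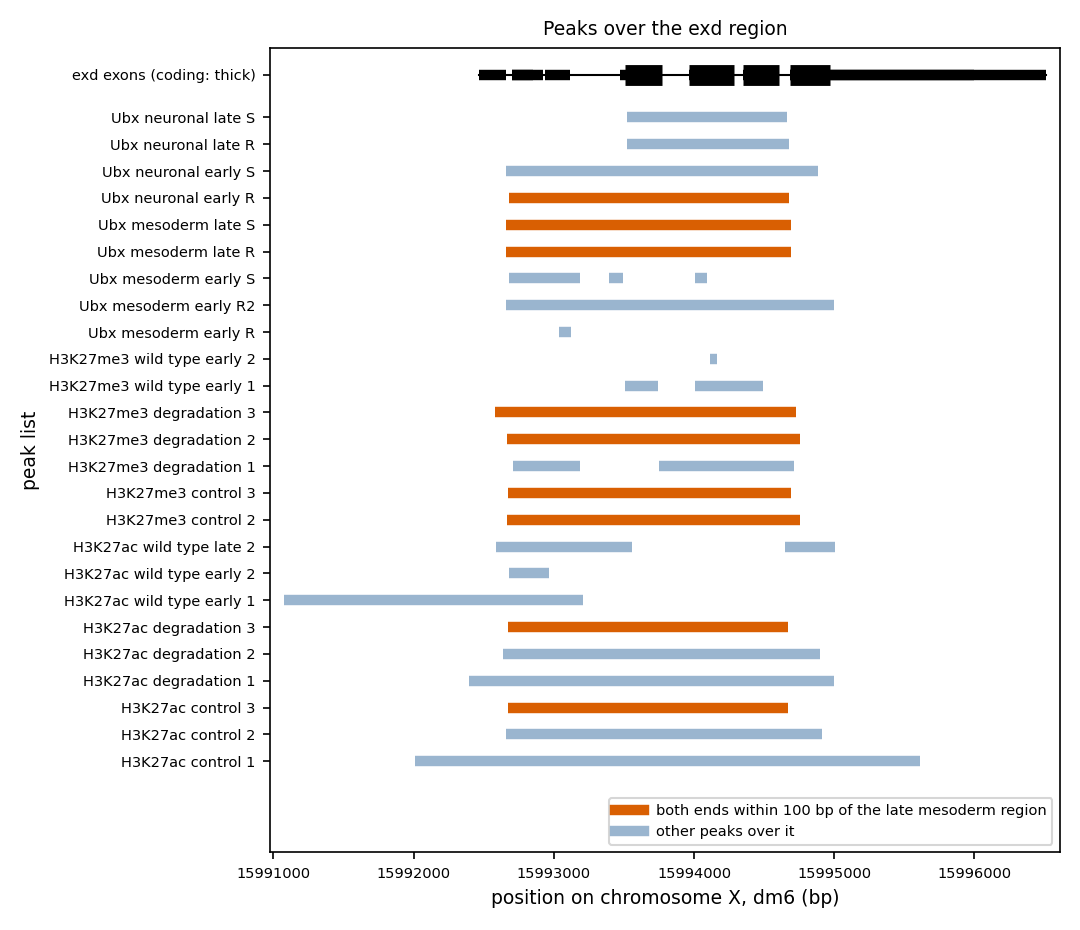
Peaks over the exd gene in each list that has one there (horizontal axis, position on X in bp; 1 line per list) with the exons of its transcripts. Peaks drawn in orange have both ends within 100 bp of the late mesoderm Ubx peak at 15992656 to 15994695, and they occur in 3 Ubx, 2 H3K27ac and 4 H3K27me3 lists.

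The Pho motif GCCAT was in 43.0% ± 0.958 of Pho control windows and 36.6% of flanking windows (ratio 1.18 ± 0.0119, n = 3), and in Ubx windows at ratios of 1.09 to 1.17 by group. The homeodomain core TAATTA was less frequent in Ubx peaks than beside them, at ratios of 0.735 ± 0.168 in early mesoderm (n = 3), 0.743 in late mesoderm, 0.632 ± 0.0130 in early neuronal nuclei and 0.946 ± 0.137 in late neuronal nuclei (n = 2 each). Of the 9 Ubx lists, late neuronal list R alone held it more often in peaks (ratio 1.04). With the better-scored 50% of peaks the late neuronal ratio turned to 1.16 ± 0.120 (1.07 and 1.24 by list), and the highest early mesoderm list was at 1.05. The composite site TGATTTAT of Hox proteins and their partner Extradenticle was at ratios of 0.630 to 0.820 by group. GAGAG, the GAGA factor site, was at 1.14 in both Pho groups and at 0.993 to 1.12 in the Ubx groups. The E-box CAGCTG was at 1.21 to 1.39, and the Twist E-box CATATG and the Mef2 site were at or under 1.09 and 0.872. In late neuronal nuclei CATATG, at 1.09, was at 1.44 in 100 bp windows, and the Mef2 site, at 0.575, was at 0.20 in 100 bp windows and 1.05 in the better-scored 50% of peaks. In every Pho and Ubx list, peak windows held more G and C than flanking windows. The shares were 48.1% against 42.9% in Pho control replicate 2 and 49.8% against 43.5% in replicate 3. GCCAT, GAGAG and CAGCTG hold more G and C than A and T. How far base composition accounts for their ratios over 1 was not tested, so these ratios do not show motif enrichment.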

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

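The alternatives were chosen before the data were examined, except that leaving out repeat peaks and leaving out the third libraries of both degradation groups were chosen after seeing the data. Of 1744 alternative values, 1382 kept their direction and their side of the threshold or moved by less than the spread, 1 was weaker, 25 were stronger, 12 were reversed and 324 moved. For single genes compared by limma, a change of sign counted as reversed only where the alternative called the gene. That rule was set knowing that 106 of the 1180 values of single genes had the other sign, and under it 1 was reversed, 25 were stronger and 128 moved. Of 188 peak counts at named genes, 92 moved. A comparison without 1 of 2 libraries of a group assumes that the lone library varies like the others. The replicate block changed no call, and the degradation comparisons gave 0 genes by limma under every alternative. The number of peaks in a list limits the Ubx comparisons. Where the library left out was the one that covered least, the others were trimmed to a longer length, so that both choices changed at once. Where no cause is named, the cause was not tested.

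Genes bound by Ubx numbered, in early mesoderm, late mesoderm and late neuronal nuclei, 12129, 7647 and 1122 with a peak in at least 1 list. In the order early mesoderm, late mesoderm, early neuronal, late neuronal, they numbered 87, 474, 5170 and 7 in the TSS window and 413, 1232, 5199 and 51 with the better-scored 50% of each list. With lists trimmed to the shortest they numbered 64, 122 and 259 in the first 3 of these groups. The authors' combined lists gave 6159 and 12040 (early mesoderm, filed with R and with R2), 7647, 5513 and 1122. Late neuronal nuclei had 69 without repeat peaks. Without 1 replicate the ranges were 1188 to 4955 in early mesoderm (4955 without R, 1757 without S), 4494 to 5785 in late mesoderm and 509 to 725 in late neuronal nuclei, which follows from asking for fewer lists. Fisher's exact test, which does not match gene length, called 4, 6, 2 and 1 of the fixed lists in the 4 groups, where matched random lists called 0.

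Between early mesoderm and early neuronal nuclei, genes bound only in mesoderm numbered 7 with trimmed lists, 12 with the better-scored 50%, 5 in the TSS window, 1 without repeat peaks and 6 to 69 without 1 replicate. Those bound only in neuronal nuclei numbered 143 with trimmed lists, 1497 in the TSS window and 864 to 4882 without 1 replicate. The difference in the share of genes with a peak was 0.705 points with trimmed lists. Between the late groups, genes bound only in mesoderm numbered 50 with trimmed lists, 1061 with the better-scored 50%, 450 in the TSS window and 2241 to 5010 without 1 replicate, and those bound only in neuronal nuclei 27, 3, 1 and 9 to 132, with 5 without repeat peaks. The difference in share was -0.451 points with trimmed lists.

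Between the stages of mesoderm, genes bound only early numbered 4 with trimmed lists, 80 with the better-scored 50%, 55 in the TSS window and 176 to 1491 without 1 replicate. Those bound only late numbered 22, 113 and 132 under the first 3 of these and 118 to 744 without 1 replicate. The difference in share was -10.5 points with replicates of the same letter paired and ran from -10.5 to 24.0 points without 1 replicate. Between the stages of neuronal nuclei, genes bound only early numbered 170 with trimmed lists, 4901 with the better-scored 50% and 5025 in the TSS window. Those bound only late numbered 30 with trimmed lists, 0 without repeat peaks and 1 to 13 without 1 replicate. The odds ratio of the overlap was 4.26 in the TSS window (Fisher's exact test, p = 0.109), and the difference in share was -0.190 points with trimmed lists.

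Between stages, limma called 0 to 1507 genes higher late for H3K27ac without 1 replicate (1507 without late replicate 2) and 0 to 688 lower (688 without early replicate 1, 8 without late replicate 2). For H3K27me3 it called 5 genes lower late on the covered share itself, 17 with the lists as deposited, 2 with the better-scored 50% and 18 in the TSS window. Without 1 replicate it called 0 to 2942 higher (2942 without late replicate 3, 824 without late replicate 2) and 7 to 59 lower. Among genes with a mean covered share of at least 10% it called 0 (lowest adjusted p 0.0853; 2 higher and 44 lower at an unadjusted p under 0.05). The gene peb ran from -55.9 points (without late replicate 3, with the others trimmed to 6.203 Mb) to 11.7 points (without late replicate 2). With a preset correlation of 0.01, camera called 2, 7, 3, 8 and 0 sets in the H3K27ac and H3K27me3 stage comparisons and the H3K27ac, H3K27me3 and Pho degradation comparisons. None held with an estimated correlation (lowest adjusted p 0.964, 0.283, 0.798, 0.144 and 0.694).

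The difference between genotypes in the gap of bound over unbound genes ran from -1.28 to 0.267 points for H3K27ac without 1 replicate. For H3K27me3 it was 0.389 points with the lists as deposited, and for Pho -0.0715 points with the lists as deposited and -0.0371 (without control replicate 3) to 0.559 points without 1 replicate. Motif ratios in 100 bp windows were 0.718 in late mesoderm and 0.601 in early neuronal nuclei for TAATTA, 0.715 and 0.689 for TGATTTAT in the same groups, 1.21 and 1.22 for GCCAT in Pho control and degradation, and 1.16 for GAGAG in Pho degradation. With the better-scored 50% of peaks they were 0.793, 0.616 and 1.16 for TAATTA in late mesoderm, early neuronal and late neuronal nuclei, 0.554 and 0.673 for TGATTTAT in early mesoderm and early neuronal nuclei, and 1.199 and 1.13 for GCCAT and GAGAG in Pho degradation. TAATTA in late neuronal nuclei thus turned from a ratio under 1 to one over 1.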

Other observations

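The tests of the exd region and the counts over other splits of the libraries were chosen after the result was seen, and the tests of repeats, homeodomain sites and base composition were written down before their deciding values were known, but after repeat shares of the best-scored peaks and motif ratios had been seen.

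Taking the 558 best-scored peaks of each Ubx list, 22 genes were hit in all 9 lists, among them the nuclear receptor gene Hr78, gpp, which encodes a histone methyltransferase, spok, an ecdysone synthesis gene, Glg1, Myo81F, Ten-a, and kl-5 and ORY on the Y chromosome. None belonged to the fixed lists. With peaks that were at least 50% repeat left out, 1 gene was hit in all 9 lists, 4.55% of the number with them, so repeated sequence may account for most of this group. TAATTA was 2.17 times as frequent in the 395 peaks behind these genes (39.0%) as in their flanks (18.0%), which is also what binding by a homeodomain protein could give. The repeats themselves may hold the motif, and the tests do not part these explanations.

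The peak over exd is a candidate site of Ubx action on its partner, or DNA with fixed ends that is not bound chromatin, such as a construct or amplified fragment. The second explanation requires the same ends in lists of other targets, and 6 of 26 such lists hold them, of histone marks as different as H3K27ac and H3K27me3. The region is not mostly repeat, since 11.5% of it is soft-masked where the X chromosome has 21.0%. The threshold for repeats was reworded after the 11.5% was seen, so this gives no independent verdict on them. Peaks with other ends cover part of it, nearly all of it or all of it in further Ubx and histone lists, which fixed ends alone do not explain. No biological explanation was tested.

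TAATTA was less frequent in Ubx peaks than beside them in 8 of the 9 lists. Among all words of 6 bases made of A and T, its ratio of peaks to flanks stood at a mean percentile of 79.7 (57.1 to 100 by list), so that base composition, with peaks richer in G and C, could account for the low ratio. A mean percentile above 90 would have argued against this. A preference for TAATTA over other such words stays open, since its percentile was above 50 in all 9 lists.

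For the degradation comparisons, the 6 libraries of a target make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes for H3K27ac, H3K27me3 and Pho by limma, and the highest of the other splits called 1, 28 and 0, so that 10, 10 and 10 splits called at least as many as the real one. With 0 real calls these counts were fixed in advance and test nothing. At an unadjusted p under 0.05 the real splits had 57, 204 and 420 genes. Where replicate numbers pair the samples, the 3 other splits that part all pairs called 0 genes and had 30 to 43 (H3K27ac) and 121 to 253 (H3K27me3) at an unadjusted p under 0.05. The 6 splits that keep a pair together had 311 to 1799 for H3K27ac, above every split that parts all pairs. This points to a structure of those samples by replicate number. For H3K27me3 they had 202 to 373, which overlaps the 121 to 253, so the counts do not show such a structure there.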
